A study of Mus musculus with 13 samples.

How the data were processed

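Libraries were made from whole blastocysts by full-length cDNA amplification for ultra-low RNA input, without molecular identifiers, so amplified copies of a molecule cannot be told from separate molecules. The deposited table holds an estimated count for each of 31528 genes on the GRCm38 build in each of 13 libraries, and the values are whole numbers. The same deposited table holds FPKM values computed by the authors. The submitters name cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d, but not the annotation or which tool counted. Between 27.2% and 34.6% of nonzero low counts (up to 100) are multiples of 4, which prompted an alternative with counts divided by 4.

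Samples were grouped by the labels into 6 groups of 2 or 3 libraries, and 10 comparisons between groups were made. Genes were kept with filterByExpr, which left 21808, and libraries were scaled by trimmed means of M values (TMM), with factors from 0.671 to 1.414. Counts were modelled with edgeR 4.0.16 quasi-likelihood tests (glmQLFit and glmQLFTest) in 1 fit of all 13 libraries with a mean per group and 7 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.9. Errors of log2 fold changes are standard errors taken from the fold change and its F value. A prior count of 2 was used for log2 CPM but not for the fold changes, so fold changes of genes near 0 counts can be very large. CPM are given as mean ± SD on the TMM scale, and summed CPM of tissue genes on the scale of library totals. Simulated changes were planted only in genes of a mean log2 CPM above 2, so recovery at lower counts was not tested. In these data the test recovered 16.4% of 4-fold, 77.6% of 16-fold and 97% of 64-fold changes between OVX and E4.5, with 6 false among 133 calls, and 29.9%, 85.1% and 100% between reduced KSOM and E4.5, with 9 false among 152.

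Groups, comparisons, gene lists, the 27 genes named in advance and the rule for naming others were fixed before the data were examined. By that rule, up to 8 genes in each direction were named for the size of their change among called genes with a mean log2 CPM of at least 4, replicates that did not overlap and a symbol that is not a predicted model, and up to 4 per list for the smallest adjusted p. The 48 lists cover metabolism, growth signalling, stress, cell cycle, lineage and tissues outside the embryo, with 1267 of their 1329 genes tested. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated and with fry. Member genes were counted over all genes and after adjustment over the list alone. Overlaps between comparisons that share controls were set against 20 simulations of groups without changes, using 9209 genes of at least 5 mean CPM for correlations.

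Alternatives fixed in advance were median-of-ratios scaling in edgeR, DESeq2 1.42.0, limma 3.58.1 on log2 of the FPKM plus 1, no low-count filter, a minimum mean CPM of 5, a fit of only the groups compared, replicate number as a block, and leaving out each library. Added after the data were seen were library totals as scaling, counts divided by 4, offsets for transcript length and GC content, and a term for the 4 libraries with muscle transcripts. The lists of tissue marker genes, the restriction to marker genes under 5 CPM in E4.5, the leave-out analysis of lists and the 8 genes drawn per library were also chosen then. A floor of 3 counts per library was used where a group had no counts, and, chosen after the data were seen, for medians of lists with many genes near 0. Work was done in R 4.3.3 and Python 3.11.15, with figures in matplotlib 3.10.9. Some single-gene results are not reported here.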

Results

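Embryonic diapause is a reversible arrest of the blastocyst before implantation. RNA from whole mouse blastocysts on the B6D2F1 background was sequenced in 13 libraries that fell into 6 groups. Blastocysts of embryonic day 4.5 from mothers on a normal diet (E4.5, n = 2) formed the reference. The other 5 groups were of day 5.5. They comprised blastocysts from ovariectomised mothers (OVX, n = 2), the hormonal way of inducing diapause, and from a starvation treatment (starvation, n = 2). A further pair of groups was cultured in KSOM, a simple defined medium for preimplantation embryos, either lacking its protein and carbohydrate components (depleted KSOM, n = 2) or with less glucose, lactate, lysine, leucine, isoleucine and arginine (reduced KSOM, n = 3). The last group came from ovariectomised mothers and was targeted with guide RNAs against Nprl2 and Tsc2 (targeted OVX, n = 2). Nprl2 belongs to the GATOR1 complex, which restrains the growth kinase complex mTORC1 when amino acids are scarce, and Tsc2 to the complex that switches off the mTORC1 activator Rheb. All induced groups were a day older than the reference, so age and treatment cannot be separated in any comparison with E4.5. The labels name no group cultured in complete KSOM. Culture itself therefore cannot be separated from the lack of nutrients where a KSOM group is compared with E4.5 or OVX. The labels do not say whether replicates are separate mothers or cultures, so the p-values measure only the spread between these samples. They do not give the sex of the embryos either, which may differ between groups. The 2 OVX libraries are named in different styles, and starvation replicate 2 carries the number 3, so these replicates may not have been made together.

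Total counts per library ran from 40678386 to 72125687, with 56038082 and 48834738 in E4.5, and 21808 genes were tested. Mitochondrially encoded transcripts took 5.88% ± 1.15 (mean ± SD) of counts in E4.5, 2.43% ± 0.198 in OVX, 6.25% ± 1.63 in starvation, 12.7% ± 0.665 in depleted KSOM, 5.48% ± 1.18 in reduced KSOM and 2.42% ± 0.53 in targeted OVX. Abundance fell with transcript length across genes, relative to the other libraries, in OVX (rank correlation −0.21 and −0.06), reduced KSOM (−0.25, −0.11 and −0.19) and targeted OVX (−0.31 and −0.25), and went the other way in E4.5 (0.04 and 0.22), starvation (0.1 and 0.35) and depleted KSOM (0.27 and 0.2). Genes are not independent replicates in such correlations. Transcripts of 13 skeletal muscle genes that were near absent from E4.5 summed to 957 CPM in OVX replicate 1 and to 809, 1120 and 718 CPM in the 3 reduced KSOM libraries, against at most 34.9 CPM elsewhere. Neutrophil transcripts moved with them, at 643 CPM in OVX replicate 1, 133 CPM in OVX replicate 2 and 1400, 1910 and 1370 CPM in reduced KSOM, against at most 32.9 CPM elsewhere. An added fit therefore carried a term for these 4 libraries. In it OVX rests on replicate 2, and the reduced KSOM values are set through the difference between the 2 OVX libraries alone.

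**Figure D1:**
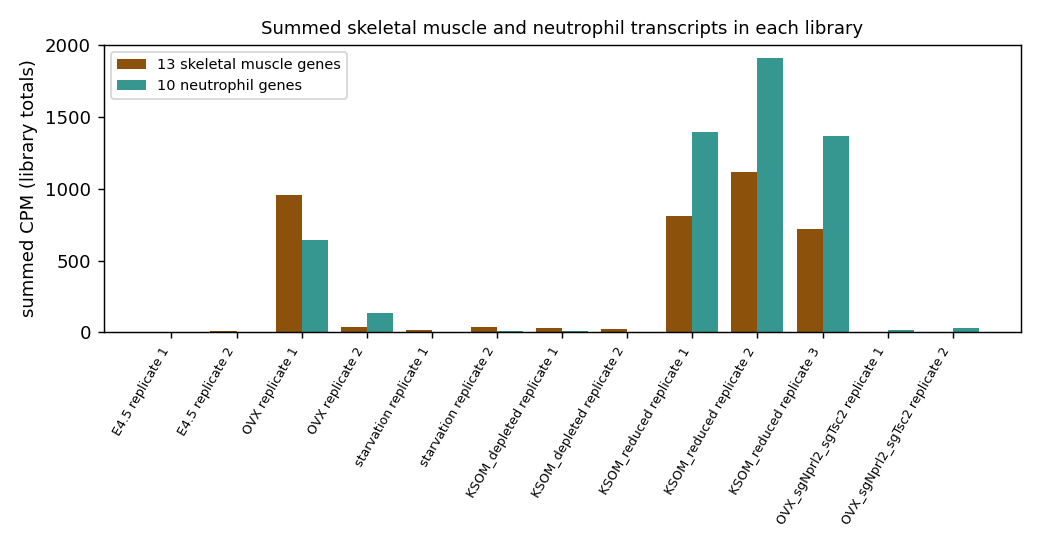
Summed CPM of 13 skeletal muscle genes and 10 neutrophil genes in each of the 13 libraries, with a brown bar for muscle and a green bar for neutrophil genes, scaled by library totals. OVX replicate 1 and the 3 reduced KSOM libraries hold 718 to 1120 CPM of the muscle genes, and no other library exceeds 34.9 CPM.

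The choice of scaling moved the centre of the data. The median log2 fold change of all genes against E4.5 was 0 in OVX, 0 in starvation, −0.09 in depleted KSOM, 0.15 in reduced KSOM and −0.16 in targeted OVX with trimmed-mean scaling. With library totals alone it was −0.53, −0.17, −0.41, −0.5 and −0.92. List medians below are on the trimmed-mean scale unless another is named. Gene lists were tested with camera at a preset correlation between genes. Only the mitochondrially encoded mRNAs between depleted KSOM and OVX were also called with an estimated correlation. Member counts come from the edgeR test over all genes unless they are said to be adjusted over the list alone.

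**Figure D2:**
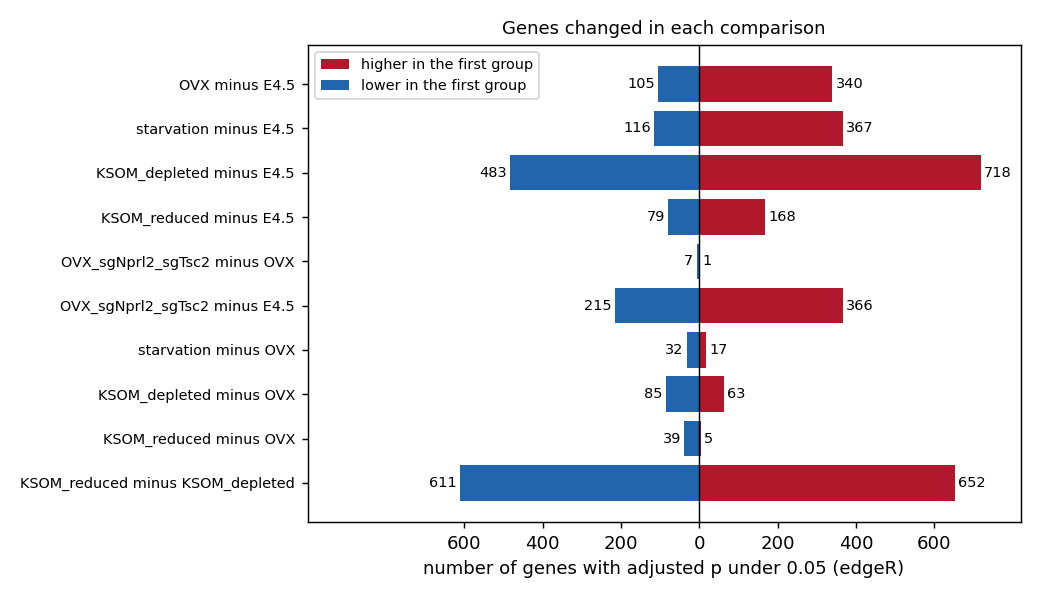
Genes called higher (red) and lower (blue) at an adjusted p under 0.05 in each of the 10 comparisons, as bars of the number of genes. The counts run from 8 genes between targeted OVX and OVX to 1263 between the 2 KSOM groups.

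The first comparison asked how blastocysts in hormonally induced diapause differed from those before it. Gchfr, which encodes the feedback regulator of GTP cyclohydrolase in tetrahydrobiopterin synthesis (ENSMUSG00000046814, chromosome 2, 119167773 to 119172390), rose 114-fold in OVX, from 4.55 ± 1.14 to 519 ± 174 CPM (mean ± SD, n = 2 and 2; adjusted p = 3.1e-05). Gsta1, a glutathione transferase, rose 188-fold (log2 fold change 7.55 ± 1.23 SE, adjusted p = 0.011), and Slc39a2, a zinc importer, rose 79.8-fold (6.32 ± 0.77, adjusted p = 0.0032). Pou5f1, which encodes the pluripotency factor OCT4 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772), was 8.61-fold lower, at 11.2 ± 2.47 against 96.7 ± 20.1 CPM (adjusted p = 0.0047). Lrp2, the endocytic receptor megalin, was 15.1-fold lower (−3.92 ± 0.57, adjusted p = 0.0066), and Gja1, the gap junction protein connexin 43, 7.71-fold lower (−2.95 ± 0.41, adjusted p = 0.0047). Of the 27 genes named in advance, Pou5f1, Cdx2, Gata6 and Foxo1 were called, all lower. Cdx2, a trophectoderm regulator, was 4.39-fold lower (adjusted p = 0.023), a call lost without E4.5 replicate 1 (adjusted p = 0.072), E4.5 replicate 2 (0.12) or OVX replicate 1 (0.13) and with the term for muscle-bearing libraries (0.13). Gata6, a primitive endoderm regulator (4.29-fold, adjusted p = 0.03), and Foxo1, a starvation-responsive transcription factor (−2.07, adjusted p = 0.045), were likewise not called without E4.5 replicate 1 (adjusted p = 0.12 and 0.23), E4.5 replicate 2 (0.07 and 0.17) or OVX replicate 1 (0.15 and 0.24).

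Nuclear genes of oxidative phosphorylation were higher in OVX by a median of 1.25, with 3 of 73 called higher, 0 lower and 70 not passing, and 38 higher and 0 lower adjusted over the list alone (adjusted p = 4.6e-17, and adjusted p = 0.38 with an estimated correlation). The median was 0.48 with library totals, 0.72 with length and GC offsets, 0.42 without OVX replicate 1 and 1.85 without OVX replicate 2. Cox6b1, a subunit of cytochrome c oxidase, was 4.35-fold higher (2.12 ± 0.48, adjusted p = 0.043), and it was not called without any 1 of E4.5 replicate 1 (adjusted p = 0.15), E4.5 replicate 2 (0.19) or OVX replicate 1 (0.19). The 13 mitochondrially encoded mRNAs of the same complexes went the other way, with 3 called lower, 0 higher and 10 not passing (7 lower and 1 higher adjusted over the list alone; median −0.97, adjusted p = 0.00011, and adjusted p = 0.38 with an estimated correlation), a call lost without OVX replicate 2 (adjusted p = 0.068), and a median of −1.68 with library totals and −1.81 with length and GC offsets. mt-Nd4l, a subunit of complex I, was 4.31-fold lower (−2.11 ± 0.35, adjusted p = 0.011), not called without E4.5 replicate 2 (adjusted p = 0.073).

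DNA replication genes of the G1/S list were lower, with 3 of 52 called lower, 0 higher and 49 not passing, and 12 lower and 2 higher adjusted over the list alone (median −0.72, −1.3 with library totals, adjusted p = 0.00014, and adjusted p = 0.38 with an estimated correlation). Pole, the catalytic subunit of DNA polymerase epsilon, was 3.82-fold lower (−1.93 ± 0.38, adjusted p = 0.023) and Mcm7, of the replicative helicase, 3.52-fold lower (adjusted p = 0.024). Neither was called once any 1 of the 4 libraries was left out, with adjusted p from 0.062 to 0.19. None of the 48 mitotic genes of the G2/M list passed, over all genes or adjusted over the list alone, at a median of −1.23 (adjusted p = 1.8e-11, and adjusted p = 0.42 with an estimated correlation). That median was −2.14 without OVX replicate 1, −0.72 without OVX replicate 2 and −2 with library totals. Heat shock genes were lower, with 3 of 21 called lower, 0 higher and 18 not passing, and 7 lower and 1 higher adjusted over the list alone (median −0.49, −1.2 with library totals, adjusted p = 0.003, and adjusted p = 0.3 with an estimated correlation). Among them Hsph1, a cochaperone of HSP70, was 4.13-fold lower (−2.05 ± 0.34, adjusted p = 0.011), a call lost without E4.5 replicate 1 (adjusted p = 0.062).

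Epiblast genes of naive pluripotency were lower in OVX, with 3 of 30 called lower, 1 higher and 26 not passing, and 5 lower and 3 higher adjusted over the list alone (median −0.87, −1.41 with library totals, adjusted p = 0.003, and adjusted p = 0.38 with an estimated correlation). The call was lost without OVX replicate 1 (median −0.58, adjusted p = 0.14). Dppa2, a chromatin regulator of early embryos, was 5.9-fold lower (−2.56 ± 0.34, adjusted p = 0.0046), while Dppa5a rose 7.84-fold (2.97 ± 0.49, adjusted p = 0.011; 0.065 without E4.5 replicate 2). Trophectoderm genes were higher, with 3 of 28 called higher, 1 lower and 24 not passing, and 6 higher and 2 lower adjusted over the list alone (median 0.62, adjusted p = 0.00096, and adjusted p = 0.3 with an estimated correlation), a call lost without E4.5 replicate 1 (adjusted p = 0.11) or OVX replicate 2 (0.21). That median was 0.05 with library totals, 0.42 without E4.5 replicate 1, 0.23 without OVX replicate 2 and 1.01 without E4.5 replicate 2. Lgals3, which encodes galectin-3, rose 11.7-fold (3.54 ± 0.36, adjusted p = 0.0011), and the tetraspanin Tspan8 13.4-fold (3.74 ± 0.4, adjusted p = 0.0016). Autophagy and lysosome genes had 6 of 47 called higher, 0 lower and 41 not passing, and 11 higher and 4 lower adjusted over the list alone. Their median was 0.36 (adjusted p = 0.013, and adjusted p = 0.38 with an estimated correlation) but −0.21 with library totals, and the call was lost without E4.5 replicate 1 (median 0.56, adjusted p = 0.058) or OVX replicate 2 (0.068). The median was 0.55 without E4.5 replicate 2. Ctsz, the lysosomal protease cathepsin Z, rose 5.62-fold (adjusted p = 0.02; 0.14 without E4.5 replicate 2).

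The test called 445 of 21808 genes between OVX and E4.5, 340 higher and 105 lower. The replicates of the 2 groups did not overlap for any of them, which chance gives 33.3% of genes. The genes were called from these same libraries, so the lack of overlap follows largely from the call. It is no separate evidence, here or in the comparisons below. The share higher was 76.4%, against 32.1% with library totals, 65.3% with length and GC offsets and 15.1% with limma on FPKM. The count was 128 without E4.5 replicate 1, 109 without E4.5 replicate 2, 284 without OVX replicate 1, 691 without OVX replicate 2 and 227 with the term for muscle-bearing libraries.

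The effect of starvation was read against the same reference. Car4, a membrane carbonic anhydrase, rose 128-fold to 636 ± 427 CPM (mean ± SD, n = 2) from 4.95 ± 3.01 CPM (n = 2; adjusted p = 0.0029), and Gchfr rose 82.1-fold (6.36 ± 0.43 SE, adjusted p = 5.7e-05). Abat, the enzyme that degrades GABA, rose 39.1-fold (5.29 ± 0.67, adjusted p = 0.0043), and Lgals3 15.2-fold (3.93 ± 0.37, adjusted p = 8e-04). Gemin5, of the complex that assembles spliceosomal particles, was 8.13-fold lower, at 4.85 ± 0.292 against 39.4 ± 0.924 CPM (adjusted p = 0.0034). Of the 27 genes named in advance 2 were called. Lifr, the LIF receptor, was 8.05-fold higher (3.01 ± 0.71, adjusted p = 0.049). Ddit4, an inhibitor of mTORC1, had no counts in either starvation library, against 1.27 ± 0.97 CPM in E4.5 (adjusted p = 0.043). That is at least 33-fold lower against a floor of 3 counts per library, but its level in E4.5 was low too, so the size of the change is uncertain. Lifr was not called without E4.5 replicate 1 (adjusted p = 0.18), E4.5 replicate 2 (0.21) or starvation replicate 2 (0.37), and Ddit4 not without any 1 of the 4 libraries (0.073 to 0.13). Pou5f1 did not pass here (−1.42 ± 0.4, adjusted p = 0.088).

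Autophagy and lysosome genes were higher in starvation, with 7 of 47 called higher, 0 lower and 40 not passing, and 11 higher and 0 lower adjusted over the list alone (median 0.63, 0.38 with library totals, adjusted p = 1.1e-05, and adjusted p = 0.1 with an estimated correlation). Ctsa, which protects lysosomal glycosidases, rose 4.13-fold (2.05 ± 0.35, adjusted p = 0.013), though not without E4.5 replicate 1 (adjusted p = 0.12) or E4.5 replicate 2 (0.076). Neu1, lysosomal sialidase, rose 4.65-fold (2.22 ± 0.42, adjusted p = 0.02), and was not called without E4.5 replicate 1 (adjusted p = 0.16) or E4.5 replicate 2 (0.076). Genes of the TCA cycle had 1 of 26 called higher, 0 lower and 25 not passing, and 9 higher and 1 lower adjusted over the list alone (median 0.89, adjusted p = 3.4e-05, and adjusted p = 0.1 with an estimated correlation). The called gene was Sdhd, an anchor of succinate dehydrogenase (3.42-fold, adjusted p = 0.027), a call lost without E4.5 replicate 1 (adjusted p = 0.21), E4.5 replicate 2 (0.12) or starvation replicate 2 (0.12). None of the 78 cytosolic ribosomal protein genes passed over all genes, and 3 were lower and 0 higher adjusted over the list alone, at a median of −0.86 (adjusted p = 2e-12, and adjusted p = 0.68 with an estimated correlation). That median was −0.55 without starvation replicate 2.

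Genes of the amino acid response driven by the transcription factor ATF4 had a median of −0.74 in starvation, with 2 of 39 called higher, 1 lower and 36 not passing, and 3 higher and 8 lower adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.54 with an estimated correlation). The list was not called without E4.5 replicate 2 (adjusted p = 0.077) or starvation replicate 1 (0.14). The G1/S list had 3 of 52 called lower, 0 higher and 49 not passing, and 13 lower and 2 higher adjusted over the list alone (median −0.78, adjusted p = 0.00022, and adjusted p = 0.53 with an estimated correlation), and was not called without starvation replicate 2 (median −0.46, adjusted p = 0.24), with a median of −1.29 without starvation replicate 1. Pold1, the catalytic subunit of DNA polymerase delta, was 5.45-fold lower (adjusted p = 0.019), not called without E4.5 replicate 1 (adjusted p = 0.14), E4.5 replicate 2 (0.1) or starvation replicate 2 (0.086). Heat shock genes had 3 of 21 called lower, 1 higher and 17 not passing, and 8 lower and 2 higher adjusted over the list alone (median −0.73, adjusted p = 0.00031, and adjusted p = 0.1 with an estimated correlation). Hsph1 was 6.53-fold lower (−2.71 ± 0.34, adjusted p = 0.0045), and the regulator Hsf2 rose 10.9-fold (3.44 ± 0.57, adjusted p = 0.013; 0.1 without E4.5 replicate 1).

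In all, 483 genes were called between starvation and E4.5, 367 higher and 116 lower, with no overlap of replicates, which chance gives 33.3% of genes. The share higher was 76% and became 49.1% with library totals, 67.5% with length and GC offsets and 30% with limma on FPKM. Without E4.5 replicate 1 the count was 55, without E4.5 replicate 2 it was 119, and without starvation replicate 1 it was 1105.

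Culture in depleted KSOM was set against E4.5 next. F3, the coagulation initiator tissue factor, rose 113-fold, from 1.08 ± 0.542 to 122 ± 48.6 CPM (mean ± SD, n = 2 and 2; adjusted p = 0.0022), and Efna1, an ephrin ligand, rose 102-fold (6.67 ± 0.92 SE, adjusted p = 0.0026). Gchfr rose 93.7-fold (6.55 ± 0.44, adjusted p = 4.4e-05) and Abat 70.7-fold (6.14 ± 0.69, adjusted p = 0.0015). Fabp5, a fatty acid carrier, was 281-fold lower, at 1.99 ± 1.61 against 559 ± 39.9 CPM (adjusted p = 0.0039). Dppa2 was 9.04-fold lower (−3.18 ± 0.35, adjusted p = 0.0015). Among the 27 genes named in advance, Pou5f1 was 4.8-fold lower (adjusted p = 0.0095; 0.069 without E4.5 replicate 1 and 0.099 without depleted KSOM replicate 2), Asns, which makes asparagine, 3.51-fold higher (adjusted p = 0.032; 0.076 without E4.5 replicate 1, 0.18 without E4.5 replicate 2 and 0.19 without depleted KSOM replicate 1), and Lifr also higher (2.74, adjusted p = 0.041; 0.069 to 0.18 without any 1 of the 4 libraries).

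Autophagy and lysosome genes were higher in depleted KSOM, with 13 of 47 called higher, 0 lower and 34 not passing, and 17 higher and 1 lower adjusted over the list alone (median 0.64, 0.3 with library totals, adjusted p = 5.9e-09, and adjusted p = 0.056 with an estimated correlation). Ctsa rose 6.04-fold (2.59 ± 0.36, adjusted p = 0.0026) and Hexa, a lysosomal glycosidase subunit, 5.21-fold (2.38 ± 0.37, adjusted p = 0.0044). Fatty acid oxidation genes had 7 of 31 called higher, 0 lower and 24 not passing, and 11 higher and 1 lower adjusted over the list alone (median 0.93, 0.61 with library totals, adjusted p = 1.7e-05, and adjusted p = 0.05 with an estimated correlation). Slc22a5, the carnitine importer, rose 11.6-fold (3.54 ± 0.58, adjusted p = 0.0062) and Acadm, a mitochondrial acyl-CoA dehydrogenase, 5.13-fold (2.36 ± 0.39, adjusted p = 0.0066). Of the 13 mitochondrially encoded mRNAs 7 were called higher, 0 lower and 6 did not pass, and 8 were higher and 0 lower adjusted over the list alone (median 1.36, adjusted p = 5.9e-09, and adjusted p = 0.22 with an estimated correlation). mt-Cytb, the cytochrome b of complex III, rose 5.12-fold (2.36 ± 0.41, adjusted p = 0.0078). Components of amino acid sensing by mTORC1 had 8 of 41 called higher, 0 lower and 33 not passing, and 10 higher and 0 lower adjusted over the list alone. Their median was 0.15 (adjusted p = 0.034, and adjusted p = 0.23 with an estimated correlation), but −0.17 with library totals and −0.06 without depleted KSOM replicate 1, and the call was also lost without E4.5 replicate 1 (median 0.27, adjusted p = 0.12) or E4.5 replicate 2 (0.051). The median was 0.35 without depleted KSOM replicate 2 and 0.08 with length and GC offsets. Rragc, a Rag GTPase that brings mTORC1 to the lysosome, rose 8.96-fold (3.16 ± 0.45, adjusted p = 0.003), and Fnip2, a partner of folliculin, 9.91-fold (adjusted p = 0.0069; 0.055 without E4.5 replicate 2).

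Cytosolic ribosomal protein genes were lower in depleted KSOM, with 15 of 78 called lower, 0 higher and 63 not passing, and 54 lower and 0 higher adjusted over the list alone (median −1.26, adjusted p = 1.6e-19, and adjusted p = 0.6 with an estimated correlation). Rpl8 of the large subunit was 4.45-fold lower (−2.15 ± 0.4, adjusted p = 0.01), not called without depleted KSOM replicate 1 (adjusted p = 0.097). The G1/S list had 15 of 52 called lower, 1 higher and 36 not passing, and 26 lower and 2 higher adjusted over the list alone (median −1.11, adjusted p = 1.5e-09, and adjusted p = 0.23 with an estimated correlation). Cdc6, which loads the replicative helicase, was 16-fold lower (−4 ± 0.65, adjusted p = 0.0057), and Mcm5, of that helicase, 9.31-fold lower (−3.22 ± 0.46, adjusted p = 0.0031). The G2/M list had 6 of 48 called lower, 0 higher and 42 not passing, and 11 lower and 0 higher adjusted over the list alone (median −1.63, adjusted p = 1.1e-10, and adjusted p = 0.61 with an estimated correlation), with a median of −2.47 without depleted KSOM replicate 1 and −1.05 without depleted KSOM replicate 2. Heat shock genes had 5 of 21 called lower, 0 higher and 16 not passing, and 8 lower and 0 higher adjusted over the list alone (median −0.81, adjusted p = 0.00015, and adjusted p = 0.056 with an estimated correlation). The median was −1.51 without depleted KSOM replicate 2, −1.49 without E4.5 replicate 2 and −1.25 with length and GC offsets. Hsph1 was 7.36-fold lower (−2.88 ± 0.35, adjusted p = 0.0019) and the chaperone Hsp90ab1 4.38-fold lower (−2.13 ± 0.35, adjusted p = 0.0056).

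Between depleted KSOM and E4.5 the test called 1201 genes, 718 higher and 483 lower, none with overlapping replicates, which chance gives 33.3% of genes. The share higher, 59.8%, was 27.9% with library totals and 29.5% with limma on FPKM. The count was 378 without E4.5 replicate 1, 540 without E4.5 replicate 2, 450 without depleted KSOM replicate 1 and 517 without depleted KSOM replicate 2.

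Reduced KSOM was set against E4.5 in the same way. Gchfr rose 88.6-fold, from 4.55 ± 1.14 to 403 ± 9.28 CPM (mean ± SD, n = 2 and 3; adjusted p = 2e-05), and was the only 1 of the 16 genes named for the size of their change to stay called without each library in turn and with the term for muscle-bearing libraries. Malat1, a nuclear noncoding RNA, rose 24.2-fold to 55600 ± 6170 CPM (adjusted p = 0.016), with adjusted p = 0.43 when that term was fitted and 0.052 to 0.06 without E4.5 replicate 1 or any reduced KSOM replicate. Ulk1, the kinase that starts autophagy, was 4.43-fold lower (−2.15 ± 0.32 SE, adjusted p = 0.014), with adjusted p = 0.42 with the term and from 0.05 to 0.075 without any 1 of the 5 libraries. Pou5f1 was 5.5-fold lower (−2.46 ± 0.36, adjusted p = 0.014; 0.5 with the term, 0.074 without E4.5 replicate 1, 0.06 without reduced KSOM replicate 1 and 0.055 without reduced KSOM replicate 3). Cdx2 and Foxo1 were the other called genes of the 27 named in advance, at −1.7 (adjusted p = 0.044) and −2.26 (adjusted p = 0.025). Neither was called with the term (adjusted p = 0.71 and 0.68) or without any 1 of the 5 libraries (0.11 to 0.27 for Cdx2 and 0.072 to 0.16 for Foxo1).

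Nuclear oxidative phosphorylation genes had 2 of 73 called higher in reduced KSOM, 0 lower and 71 not passing, and 42 higher and 0 lower adjusted over the list alone. Their median was 1.25 (adjusted p = 2.6e-18, and adjusted p = 0.5 with an estimated correlation), but 0.72 with length and GC offsets, 0.56 with library totals and −0.21 with the term for muscle-bearing libraries, where the list was called lower (adjusted p = 0.048). Cox6b1 was 5.47-fold higher (2.45 ± 0.46, adjusted p = 0.03), with adjusted p = 0.71 with the term and 0.075 to 0.14 without any 1 of the 5 libraries. Heat shock genes had 2 of 21 called lower, 0 higher and 19 not passing, and 7 lower and 1 higher adjusted over the list alone (median −0.51, −1.19 with library totals, adjusted p = 5.8e-05, and adjusted p = 0.15 with an estimated correlation). Hsph1 was 4.71-fold lower (−2.24 ± 0.29, adjusted p = 0.0098), with adjusted p = 0.23 with the term and 0.06 without reduced KSOM replicate 1. Naive pluripotency genes had 5 of 30 called lower, 1 higher and 24 not passing, and 7 lower and 1 higher adjusted over the list alone (median −0.96, −1.65 with library totals, adjusted p = 2.8e-05, and adjusted p = 0.35 with an estimated correlation). With the term their median was −0.1 and the call was lost (adjusted p = 0.19). Tet2, a DNA demethylase, was 3.22-fold lower (−1.69 ± 0.33, adjusted p = 0.032), with adjusted p = 0.37 with the term and from 0.1 to 0.26 without any 1 of the 5 libraries.

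The comparison of reduced KSOM with E4.5 called 247 genes, 168 higher and 79 lower, with no overlap of replicates, which chance gives 20% of genes. The share higher was 68%, against 15% with library totals, 53.3% with length and GC offsets and 16.6% with limma on FPKM. With the term for muscle-bearing libraries 2 genes were called. The count was 46 without E4.5 replicate 1, 38 without E4.5 replicate 2, and 9, 37 and 31 without reduced KSOM replicates 1, 2 and 3.

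Across the 4 ways of inducing diapause, 50 genes were called against E4.5 in every one, 41 higher and 9 lower in each. Simulated groups without changes, set against shared E4.5 libraries that were simulated too, had 0.05 such genes on average and at most 1 in 20 simulations. The simulations hold no difference of age, so they cannot tell shared effects of the inductions from the day of age common to all 4 groups. They draw each gene independently, so trends across a library, such as that with transcript length, are not in them either. With only 2 control libraries, their chance deviations enter all 4 comparisons. Gchfr was among the 41 (6.83, 6.36, 6.55 and 6.47 in OVX, starvation, depleted KSOM and reduced KSOM). So were the lysosomal enzymes Lgmn and Fuca1, with log2 fold changes in the same order of 2.76, 2.78, 2.95 and 1.7 for Lgmn. Lgals3 (3.54, 3.93, 2.63 and 2.8), the alcohol dehydrogenase Adh1 (4.84, 4.54, 5.13 and 4.13) and the tissue factor F3 (5.76, 4.65, 6.82 and 4.43) were others. The 9 lower genes included Hsph1 (−2.05, −2.71, −2.88 and −2.24), Gja1 (−2.95, −2.17, −2.59 and −1.95) and the nuclear import receptors Kpnb1 and Ipo7 (−1.92, −1.97, −2.27 and −1.71 for Kpnb1). The share higher was 82%, against 35.5% with library totals, 71% with length and GC offsets and 6.3% with limma on FPKM. The count of 50 was 12 without E4.5 replicate 1, 19 without E4.5 replicate 2, 92 without OVX replicate 2, 141 and 77 without starvation replicates 1 and 2, and 7, 15 and 13 without reduced KSOM replicates 1, 2 and 3. It was 2 with the term for muscle-bearing libraries.

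**Figure D3:**
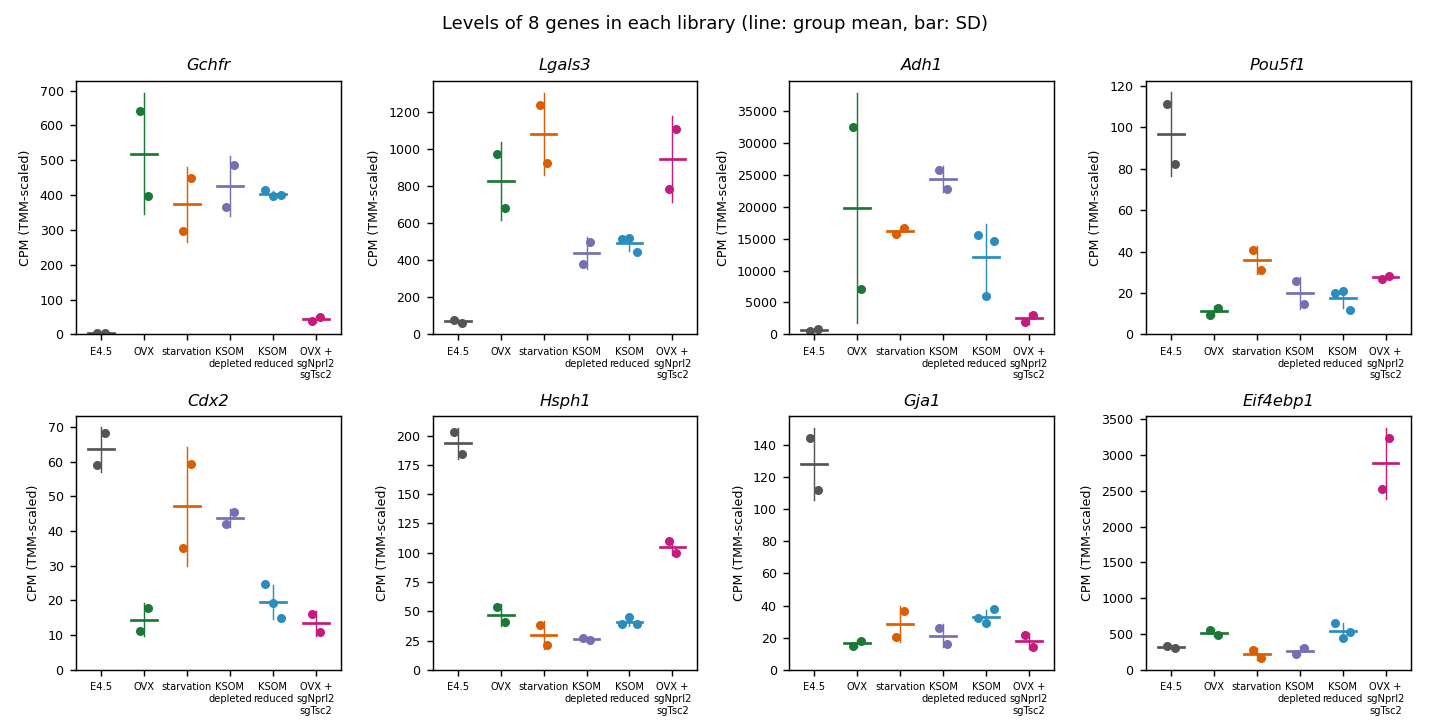
CPM scaled by trimmed means, on linear axes, of Gchfr, Lgals3, Adh1, Pou5f1, Cdx2, Hsph1, Gja1 and Eif4ebp1 in each of the 13 libraries; points are libraries, lines the group mean and bars the SD. Gchfr stands at 4.55 CPM in E4.5, between 374 and 519 CPM in the 4 untargeted day 5.5 groups and at 44.1 CPM in targeted OVX, and Eif4ebp1 is highest in targeted OVX at 2880 CPM.

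Fold changes across 9209 genes correlated more than shared controls alone gave for OVX and reduced KSOM (r = 0.78, against 0.56 in simulation) and for starvation and depleted KSOM (r = 0.67, against 0.5). OVX with starvation (0.53 against 0.5, highest 0.54) lay within the simulated range, and with depleted KSOM (0.56 against 0.51, highest 0.55) just above it. Starvation with reduced KSOM (0.39 against 0.55) and the 2 KSOM groups (0.44 against 0.56) lay below it. The covariance exceeded its simulated 0.25 in each of these 6 pairs, from 0.65 for starvation and reduced KSOM to 1.45 for OVX and reduced KSOM. These are correlations across genes, which are not independent replicates, and the pair with r = 0.78 shares the libraries with muscle transcripts. The day of age between E4.5 and the other groups is not part of the simulations. Nor are trends across a library, since genes were drawn independently. Relative to the other libraries, abundance fell with transcript length in OVX and reduced KSOM and rose with it in starvation and depleted KSOM. These are the pairs with the clearest excess, and the part of such trends in it was not tested.

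Targeting of Nprl2 and Tsc2 was compared with untargeted OVX to ask what differed with it in blastocysts of ovariectomised mothers. The labels name no OVX group given control guides. Delivery of the guides and handling of the embryos thus cannot be separated from the loss of these genes. Eif4ebp1, a translation repressor that mTORC1 inactivates and ATF4 induces, rose 5.58-fold, from 516 ± 49.4 to 2880 ± 495 CPM (mean ± SD, n = 2 and 2; adjusted p = 0.042). Its call was lost without targeted replicate 2 (adjusted p = 0.062) and with the term for muscle-bearing libraries (0.05). Gchfr was 11.8-fold lower, at 44.1 ± 7.94 against 519 ± 174 CPM (adjusted p = 0.01), which still left it above E4.5 by 3.28 on the log2 scale (adjusted p = 0.0027). Emp2, a tetraspan membrane protein, was 8.58-fold lower (−3.1 ± 0.35 SE, adjusted p = 0.01). Mettl27, Crym, Cryl1 and Mlycd, named after their values were seen, were also called lower. Mlycd, malonyl-CoA decarboxylase, had no counts in targeted OVX, against 6.12 ± 0.548 CPM in OVX (adjusted p = 0.026). With a floor of 3 counts per library it was at least 76.1-fold lower. None of the 27 genes named in advance passed. Nprl2 itself had 13.9 and 28.6 CPM in targeted OVX against 38 and 36.5 in OVX (−0.81 ± 0.52, adjusted p = 0.55), and Tsc2 14.7 and 8.26 against 23.3 and 14.1 (−0.7 ± 0.49, adjusted p = 0.58). Guides edit DNA, so transcript levels say little about whether the edit worked.

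The amino acid response list was higher in targeted OVX than in OVX, with 1 of 39 called higher, 0 lower and 38 not passing, and 8 higher and 0 lower adjusted over the list alone (median 0.98, adjusted p = 2.4e-13, and adjusted p = 0.12 with an estimated correlation). After Eif4ebp1 the members with the smallest p were Ddit3, which encodes CHOP (2.28 ± 0.45, adjusted p = 0.098), Psat1, of serine synthesis (2.09 ± 0.46, adjusted p = 0.12), and Trib3, a stress-induced pseudokinase (3.75 ± 0.86, adjusted p = 0.13). None of the 20 cytosolic aminoacyl-tRNA synthetases passed, over all genes or adjusted over the list alone, at a median of 0.49 (adjusted p = 7.7e-05, and adjusted p = 0.37 with an estimated correlation). None of the 78 ribosomal protein genes passed either way, at a median of 0.65 (adjusted p = 1.7e-13, and adjusted p = 0.47 with an estimated correlation), and the median was 0.15 and not called without OVX replicate 2 (adjusted p = 0.17), 1.2 without OVX replicate 1 and 0.29 without targeted replicate 1. Ribosome biogenesis genes had 0 of 55 called, and 1 higher and 0 lower adjusted over the list alone (median 0.31, adjusted p = 1.6e-05, and adjusted p = 0.3 with an estimated correlation). Their median was 0.2 without targeted replicate 1, 0.11 with library totals and 0.49 with length and GC offsets. The G2/M list had 0 of 48 called either way at a median of 0.76 (adjusted p = 5.3e-11, and adjusted p = 0.47 with an estimated correlation), which was 0.28 without OVX replicate 2 (adjusted p = 0.06), 1.71 without OVX replicate 1 and 0.41 without targeted replicate 1. Autophagy and lysosome genes were lower, with 0 of 47 called over all genes and 2 lower and 0 higher adjusted over the list alone (median −0.6, −0.37 with length and GC offsets, adjusted p = 0.001, and adjusted p = 0.3 with an estimated correlation). The members with the smallest p included Neu1 (−2.12 ± 0.42, adjusted p = 0.098), and Ctsa (−1.61 ± 0.34, adjusted p = 0.12). Lists of cells outside the embryo were lower too. Blood cell genes had 0 of 22 called over all genes and 4 lower and 0 higher adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.69 with an estimated correlation). Their median was −2.38 with a floor of 3 counts per library, and the call was lost without OVX replicate 1 (adjusted p = 0.17) or targeted replicate 1 (0.096) and with the term for muscle-bearing libraries (0.091). Fibroblast and stroma genes had 0 of 12 called either way (median −0.56 at that floor, adjusted p = 0.027, and adjusted p = 0.3 with an estimated correlation), a call lost without targeted replicate 1 (adjusted p = 0.17) and with that term (0.054).

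The edgeR test called 8 genes here, 1 higher and 7 lower, and 2372 genes had an unadjusted p under 0.05. The replicates of the called genes did not overlap, which chance gives 33.3% of genes. The share higher was 12.5% and 60% with limma on FPKM. The count was 116 without OVX replicate 1, 103 without OVX replicate 2, 179 and 22 without targeted replicates 1 and 2, and 54 with the term for muscle-bearing libraries. In simulated data with the spread of these libraries the test recovered 17.9% of 4-fold, 80.6% of 16-fold and 93.9% of 64-fold changes. These were planted only in genes of a mean log2 CPM above 2.

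Against E4.5, targeted OVX showed where the targeted blastocysts stood relative to the stage before diapause. Nupr1, a stress-induced chromatin protein, rose 110-fold to 2370 ± 355 CPM (mean ± SD, n = 2) from 21.4 ± 11.1 CPM (n = 2; adjusted p = 0.01), and Ctsc, the protease cathepsin C, 24.9-fold (4.64 ± 0.72 SE, adjusted p = 0.0091). Aldh1l1, a folate enzyme, was 9.82-fold lower (−3.3 ± 0.45, adjusted p = 0.0057), and Gja1 was lower (−2.83, adjusted p = 0.0072). Of the 27 genes named in advance Pou5f1, Cdx2 and Foxo1 were lower and Asns higher, none of them called without E4.5 replicate 2 (adjusted p = 0.095 for Cdx2, 0.14 for Foxo1 and 0.27 for Asns) or targeted replicate 2 (0.11, 0.16 and 0.11), and Pou5f1 not without any 1 of the 4 libraries (0.11 to 0.2). The amino acid response list had 8 of 39 called higher, 0 lower and 31 not passing, and 14 higher and 0 lower adjusted over the list alone (median 1.34, 0.56 with library totals, 0.92 without targeted replicate 2, adjusted p = 2.5e-11, and adjusted p = 0.2 with an estimated correlation). Eif4ebp1 rose 8.91-fold (3.15 ± 0.38, adjusted p = 0.003), and Psph, the last enzyme of serine synthesis, 9.33-fold (3.22 ± 0.56, adjusted p = 0.012; 0.082 without E4.5 replicate 2). Nuclear oxidative phosphorylation genes had 11 of 73 called higher, 0 lower and 62 not passing, and 44 higher and 0 lower adjusted over the list alone (median 1.42, adjusted p = 8e-26, and adjusted p = 0.44 with an estimated correlation), with medians of 0.68 with length and GC offsets and 0.65 with library totals. Ndufb5, of complex I, rose 4.48-fold (2.16 ± 0.37, adjusted p = 0.012; 0.063 without E4.5 replicate 1 and 0.1 without E4.5 replicate 2). The G1/S list had 4 of 52 called lower, 0 higher and 48 not passing, and 12 lower and 2 higher adjusted over the list alone (median −0.81, −1.6 with library totals, adjusted p = 0.0053, and adjusted p = 0.54 with an estimated correlation), a call lost without E4.5 replicate 1 (adjusted p = 0.077). Ribosomal protein genes had 1 called higher, 1 lower and 76 not passing, and 10 higher and 1 lower adjusted over the list alone, at a median of 0.76 (adjusted p = 6e-10, and adjusted p = 0.59 with an estimated correlation) that was −0.01 with library totals, 0.2 with length and GC offsets and 0.4 without targeted replicate 1. The test called 581 genes, 366 higher and 215 lower, with no overlap of replicates, which chance gives 33.3% of genes. The share higher, 63%, was 14.1% with library totals and 15% with limma on FPKM. The count was 185 without E4.5 replicate 1, 82 without E4.5 replicate 2, 239 without targeted replicate 2 and 963 with the term for muscle-bearing libraries.

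**Figure D4:**
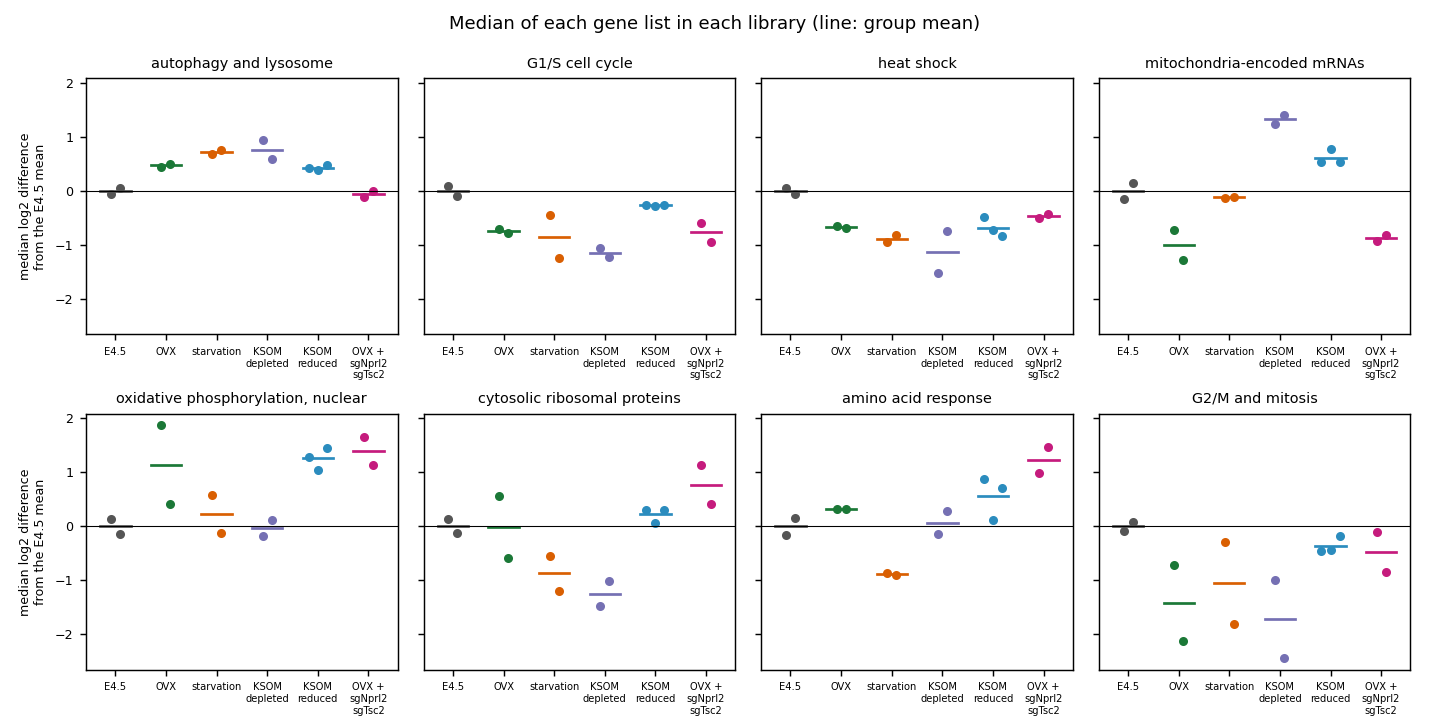
Median log2 difference from the E4.5 mean over the genes of 8 lists, 1 point per library and a line at the group mean. The amino acid response list stands at 0.99 and 1.48 in targeted OVX, 0.33 and 0.33 in OVX and −0.86 and −0.89 in starvation, while ribosomal proteins stand at −1.48 and −1.01 in depleted KSOM and spread from −0.59 to 0.57 between the 2 OVX libraries.

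The ways of inducing diapause were then compared with OVX directly. In starvation, Aldh2, mitochondrial aldehyde dehydrogenase, was 6.55-fold higher (2.71 ± 0.37 SE, n = 2 and 2, adjusted p = 0.02; 0.055 without OVX replicate 1), and Ldha, lactate dehydrogenase A, 8.41-fold lower, at 18 ± 8.08 against 152 ± 44.8 CPM (adjusted p = 0.027). Tmem37, a membrane protein, was 14.2-fold lower (−3.83 ± 0.5, adjusted p = 0.02). None of the 16 genes named for the size of their change stayed called with the term for muscle-bearing libraries. None of the 78 ribosomal protein genes passed over all genes and 12 were lower and 0 higher adjusted over the list alone (median −0.93, adjusted p = 1.4e-16, and adjusted p = 0.59 with an estimated correlation), and the median was −0.32 without OVX replicate 1, −0.47 with library totals, −0.43 with length and GC offsets and −0.31 with that term. The amino acid response list had 0 of 39 called over all genes, and 8 lower and 1 higher adjusted over the list alone (median −0.82, −0.46 with library totals, adjusted p = 5.3e-05, and adjusted p = 0.35 with an estimated correlation). Targets of ERK signalling had 0 of 19 called over all genes and 5 higher and 0 lower adjusted over the list alone (median 1.27, adjusted p = 0.00021, and adjusted p = 0.35 with an estimated correlation), with a median of 2.38 without OVX replicate 2. Starvation and OVX differed in 49 genes, 17 higher and 32 lower, without overlap of replicates (33.3% by chance). The share higher, 34.7%, was 78.6% with library totals, 46.7% with length and GC offsets and 76.4% with limma on FPKM. The count was 31 and 660 without OVX replicates 1 and 2, 220 and 210 without starvation replicates 1 and 2, and 2 with the term for muscle-bearing libraries.

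Depleted KSOM was compared with OVX next. Of the 13 mitochondrially encoded mRNAs 6 were called higher, 0 lower and 7 did not pass, and all 13 were higher adjusted over the list alone (median 1.91, adjusted p = 5.5e-28, and adjusted p = 0.044 with an estimated correlation). mt-Nd4l rose 11.5-fold, from 54.2 ± 11.8 to 622 ± 14.4 CPM (mean ± SD, n = 2 and 2; adjusted p = 0.003), and mt-Cytb 6.58-fold (2.72 ± 0.42 SE, adjusted p = 0.017). Nuclear oxidative phosphorylation genes had 0 of 73 called over all genes and 47 lower and 2 higher adjusted over the list alone (median −1.51, adjusted p = 3.8e-15, and adjusted p = 0.55 with an estimated correlation), with a median of −0.43 without OVX replicate 1 or with the term for muscle-bearing libraries and −0.58 with length and GC offsets. Ribosomal protein genes had 0 of 78 called over all genes and 65 lower and 0 higher adjusted over the list alone (median −1.35, adjusted p = 2.2e-29, and adjusted p = 0.42 with an estimated correlation), with a median of −0.75 without OVX replicate 1, −0.74 with that term and −0.71 with length and GC offsets. Pan3, of the deadenylase complex that shortens poly(A) tails, rose 9.64-fold (3.27 ± 0.46, adjusted p = 0.011). Pla2g10, a secreted phospholipase, was 83.6-fold lower (−6.38 ± 0.78, adjusted p = 0.009), and Ldha 11.6-fold lower (−3.53 ± 0.46, adjusted p = 0.01). The test called 148 genes, 63 higher and 85 lower, without overlap of replicates (33.3% by chance). The share higher, 42.6%, was 52.7% with library totals and 64.2% with limma on FPKM. The count was 97 and 934 without OVX replicates 1 and 2, 41 and 43 without depleted KSOM replicates 1 and 2, and 42 with the term for muscle-bearing libraries.

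Reduced KSOM differed from OVX in 44 genes, 5 higher and 39 lower, without overlap of replicates (20% by chance). Tmem37 was 23.9-fold lower, at 8.85 ± 1.28 against 212 ± 15 CPM (mean ± SD, n = 3 and 2; adjusted p = 0.0029), and not called without reduced KSOM replicate 1 (adjusted p = 0.068) or 2 (0.073). Of the mitochondrially encoded mRNAs 2 of 13 were called higher, 0 lower and 11 did not pass, and all 13 were higher adjusted over the list alone (median 1.24, adjusted p = 1.2e-16, and adjusted p = 0.19 with an estimated correlation). mt-Nd3 rose 6.31-fold (2.66 ± 0.42 SE, adjusted p = 0.024), with adjusted p from 0.11 to 0.14 without any 1 reduced KSOM replicate, 0.084 without OVX replicate 2 and 0.14 with the term for muscle-bearing libraries. Trophectoderm genes had 1 of 28 called lower, 0 higher and 27 not passing, and 8 lower and 1 higher adjusted over the list alone (median −0.58, adjusted p = 7.5e-06, and adjusted p = 0.25 with an estimated correlation), with a median of −0.34 without OVX replicate 2 or with that term. The called member was Tspan8, 4.28-fold lower (−2.1 ± 0.33, adjusted p = 0.024), and not called without any 1 reduced KSOM replicate (adjusted p from 0.14 to 0.2). The share higher, 11.4%, was 54.6% with limma on FPKM. The count was 229 without OVX replicate 1, 13 with the term for muscle-bearing libraries and 1 without reduced KSOM replicate 3. It was 0 by edgeR without reduced KSOM replicate 1 or 2, where 1444 and 1497 genes had an unadjusted p under 0.05, and with all libraries DESeq2 called 880 genes and limma 119.

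The 2 culture media were compared to ask what the nutrients left in reduced KSOM changed. Ribosomal protein genes were higher in reduced than in depleted KSOM, with 34 of 78 called higher, 0 lower and 44 not passing, and 63 higher and 0 lower adjusted over the list alone (median 1.41, adjusted p = 1.3e-25, and adjusted p = 0.4 with an estimated correlation). The median was 0.88 with length and GC offsets, and 0.42 and no longer called with the term for muscle-bearing libraries (adjusted p = 0.16). Rpl37a rose 5.57-fold, from 393 ± 104 to 2190 ± 220 CPM (mean ± SD, n = 2 and 3; adjusted p = 0.014), with adjusted p = 0.11 without depleted KSOM replicate 1 and 0.053 without reduced KSOM replicate 1. The G1/S list had 10 of 52 called higher, 1 lower and 41 not passing, and 17 higher and 1 lower adjusted over the list alone (median 0.96, 0.58 with library totals, adjusted p = 3.7e-06, and adjusted p = 0.4 with an estimated correlation). Tk1, thymidine kinase, rose 11-fold (3.46 ± 0.6 SE, adjusted p = 0.012; 0.07 without depleted KSOM replicate 1). Nuclear oxidative phosphorylation genes had 20 of 73 called higher, 1 lower and 52 not passing, and 45 higher and 2 lower adjusted over the list alone (median 1.4, adjusted p = 1.2e-10, and adjusted p = 0.59 with an estimated correlation), with medians of 0.66 with length and GC offsets and −0.26 with the term for muscle-bearing libraries, where the list was called lower (adjusted p = 0.022).

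Autophagy and lysosome genes were lower in reduced than in depleted KSOM, with 11 of 47 called lower, 0 higher and 36 not passing, and 15 lower and 0 higher adjusted over the list alone (median −0.59, adjusted p = 2.5e-06, and adjusted p = 0.09 with an estimated correlation). The median was −0.38 without depleted KSOM replicate 1, −0.95 with library totals and −0.37 with length and GC offsets. Ulk1 was 5.01-fold lower (−2.32 ± 0.32, adjusted p = 0.0055). Fatty acid oxidation genes had 5 of 31 called lower, 0 higher and 26 not passing, and 12 lower and 1 higher adjusted over the list alone (median −0.49, mean −0.03, adjusted p = 0.00016, and adjusted p = 0.09 with an estimated correlation). Their median was −0.87 with library totals and −0.75 with length and GC offsets. Slc22a5 was 5.99-fold lower (−2.58 ± 0.48, adjusted p = 0.015), and not called without depleted KSOM replicate 1 (adjusted p = 0.057) or any 1 reduced KSOM replicate (0.06 to 0.07). Fxyd4, a regulator of the sodium pump, rose 14.8-fold (3.89 ± 0.4, adjusted p = 0.0016), and Pan3 was 18.1-fold lower (−4.18 ± 0.41, adjusted p = 0.0016).

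Between the media the test called 1263 genes, 652 higher and 611 lower in reduced KSOM, without overlap of replicates (20% by chance). The share higher, 51.6%, was 38.8% with library totals and 39.1% with limma on FPKM. The count was 148 and 225 without depleted KSOM replicates 1 and 2, and 133, 202 and 121 without reduced KSOM replicates 1, 2 and 3. With the term for muscle-bearing libraries edgeR called 0 genes, with 1687 at an unadjusted p under 0.05, and without it DESeq2 called 4119 and limma 2368. All 3 reduced KSOM libraries held at least 718 CPM of the muscle genes and the depleted KSOM libraries 27.5 and 20.9 CPM, so the medium and that source cannot be told apart in these data.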

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

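The 3 tests of where the muscle transcripts came from, the batch tests of reduced KSOM and targeted OVX and the error margins were chosen after the results were seen. The SE of a list median below is taken over the genes of the list, which are not independent. It does not measure the spread between libraries.

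Transcripts of 13 skeletal muscle genes summed to 957 CPM in OVX replicate 1 and to 809, 1120 and 718 CPM in reduced KSOM replicates 1, 2 and 3, and neutrophil transcripts to 643, 1400, 1910 and 1370 CPM. The muscle genes had nearly the same profile in the 4 libraries (lowest r = 0.978), so 1 outside source shared by them is a candidate explanation, though muscle RNA from separate sources might share a profile too. Expression by the embryos stays open, since OVX replicate 2 held 3.64% of the muscle sum of replicate 1 but 20.6% of its neutrophil sum, and the pattern was noticed through replicate 1 itself. Uterine tissue stays open as well, since 8 of its genes reached at most 1.82% of the muscle sum, but 20.3% with Ltf and Lcn2, which neutrophils also express. Camera called the list of uterine genes fixed in advance higher than in E4.5 in reduced KSOM (adjusted p = 1.1e-05, and adjusted p = 0.34 with an estimated correlation). The single genes called in that list were again Ltf and Lcn2, so the list is not wholly separate evidence. The ratio of neutrophil to muscle transcripts, 0.672 in OVX replicate 1 and 1.71 to 1.91 in reduced KSOM, was not the same, and what the source was stays open.

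The list of nuclear oxidative phosphorylation genes was called higher than in E4.5 in OVX, reduced KSOM and targeted OVX by camera at the preset correlation. It was called in none of the 3 with an estimated correlation, and most of its genes did not pass over all genes. Transcript length and GC content are argued against as the whole cause, since the lowest of the 3 medians was still 0.68 (SE 0.12) with offsets for them, though they may explain part. Muscle transcripts do not account for targeted OVX, whose libraries hold at most 2.05 CPM of them and had medians of at least 1.13. Their absence does not show that these libraries were made apart from the muscle-bearing ones. Airway epithelium genes were found in both targeted libraries (25.5 and 31 CPM) and in reduced KSOM replicates 1 and 3 (57.2 and 60.9 CPM). A batch other than the muscle transcripts was not tested. The batch of libraries with muscle transcripts cannot be told apart from the treatment for OVX, where replicate 2 had 0.41. The same holds for reduced KSOM, at −0.21 with the added term, a value set by the 2 OVX libraries. Scaling stays open for the size of the rise, with a lowest median of 0.48 with library totals. The list stood above the other genes on that scale too. Its medians were 0.48, 0.56 and 0.65 in OVX, reduced KSOM and targeted OVX, against −0.53, −0.5 and −0.92 for all genes. The day of age between E4.5 and the other groups was not tested.

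The amino acid response and ribosomal protein lists were called higher in targeted OVX than in OVX by camera at the preset correlation. Neither was called with an estimated correlation, and of their genes only Eif4ebp1 passed over all genes. Against OVX replicate 2 alone the ribosomal protein median was 1.2 (SE 0.11 over its genes), which argues against OVX replicate 1 alone as its cause. Without OVX replicate 2 that median was 0.15, so its size rests on that library. The amino acid response median was 0.89, past the bound of 0.5 set beforehand, with an error of 0.51 from the SD of its genes and 0.26 from their median deviation, so it stays open under the first and not under the second, and both errors were chosen after the values were seen. Transcript length and GC content are argued against for the amino acid response list (1.23, SE 0.41) but stay open for ribosomal proteins (0.54, SE 0.09). The targeting itself, the difference that the design names, was not tested as a cause. Without a group given control guides, it cannot be told apart from delivery of the guides and handling.

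Of the 1263 genes called between the KSOM media, 794 had fold changes against E4.5 of opposite sign, but 0 of them were called by edgeR against E4.5 in both media and 171 in 1. The genes were chosen for their difference between the media, which favours opposite signs, and the share among all genes is not given. The 794 are therefore no evidence that the media act in opposite directions. Among the 1263 genes, 34 ribosomal proteins were higher in reduced KSOM. The muscle-bearing libraries are all those of reduced KSOM here, so medium and source were not separated.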

How the results depend on the processing

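Library totals, counts divided by 4, length and GC offsets, the term for muscle-bearing libraries and leave-out medians of lists were chosen after results were seen. Counts of called genes follow 1 order: OVX, starvation, depleted KSOM, reduced KSOM and targeted OVX against E4.5 (445, 483, 1201, 247 and 581), then targeted OVX, starvation, depleted KSOM and reduced KSOM against OVX (8, 49, 148 and 44), reduced against depleted KSOM (1263), and the shared genes (50). Median-of-ratios scaling gave 428, 462, 1172, 235 and 587, then 7, 53, 144 and 42, 1187, and 52. Library totals gave 287, 230, 980, 545 and 764, then 7, 28, 110 and 24, 1259, and 31. Without a low-count filter the counts were 1470, 1473, 2370, 1226 and 1638, then 636, 1091, 1417 and 589, 2652, and 274. The filter at a mean CPM of 5 gave 888, 978, 1697, 499 and 1039, then 10, 272, 384 and 117, 1819, and 125. Counts divided by 4 gave 655, 699, 1554, 355 and 780, then 6, 103, 206 and 76, 1700, and 81. Length and GC offsets gave 449, 465, 1204, 306 and 434, then 8, 60, 139 and 36, 934, and 62. DESeq2 gave 2393, 2782, 3747, 2083 and 3064, then 1242, 2062, 2330 and 880, 4119, and 475. limma on FPKM gave 1584, 1449, 2305, 1834 and 1933, then 20, 258, 400 and 119, 2368, and 415. Replicate number as a block gave 312, 311, 1008, 59 and 380, then 4, 0, 73 and 3, 479, and 20. The 0 is of edgeR, with 2592 genes at an unadjusted p under 0.05. No sign of pairing by replicate number was seen, with 30 correlations of deviations between −0.059 and 0.073. Between groups of 2 libraries, replicates 1 and 2 give the same value by construction, so the 30 are not all separate. In fits of only the groups compared edgeR gave 0, 0, 2212, 2462 and 0, then 0, 0, 0 and 26, 4455, and 0 shared. Unadjusted p under 0.05 held there for 3334 genes in OVX, 2942 in starvation and 4165 in targeted OVX against E4.5, and for 1272, 1466 and 2795 in targeted OVX, starvation and depleted KSOM against OVX. The term for muscle-bearing libraries gave 227, 678, 1505, 2 and 963, then 54, 2, 42 and 13, 0, and 2. The 0 is of edgeR, with 1687 genes at an unadjusted p under 0.05. Leaving out each library gave 109 to 691, 55 to 1105, 378 to 540, 9 to 46 and 82 to 791, then 22 to 179, 31 to 660, 41 to 934 and 0 to 229, 121 to 225, and 7 to 141 shared. The 0 came from edgeR without reduced KSOM replicate 1 or 2, with 1444 and 1497 genes at an unadjusted p under 0.05. Of 1118 results for single genes the term for muscle-bearing libraries left 866 as they were, weakened 226, strengthened 24 and reversed 2, and median-of-ratios scaling left 1092. Of 130 list calls, 1 was kept with an estimated correlation and 41 with fry. Some list medians changed sign, or their test changed direction. With library totals several lists in targeted OVX against E4.5 turned negative, where the median of all genes was −0.92. They included translation (−0.52), MYC targets (−0.44), ribosome biogenesis (−0.41), aminoacyl-tRNA synthetases (−0.38) and amino acid transporters (−0.11). In reduced KSOM against E4.5 glycolysis was −0.03 and the mitochondrially encoded mRNAs −0.02 on that scale. The mitochondrially encoded mRNAs in reduced KSOM against E4.5 were −0.36 with length and GC offsets. With the term for muscle-bearing libraries they were 0.34 and not called, and oxidative phosphorylation was −0.21 in reduced KSOM against E4.5 and −0.26 against depleted KSOM. The G2/M list was −0.2 between the media with that term. The list of blood cell genes, many at or near 0 counts so that its medians rest on fitted values (4.28 in reduced KSOM against E4.5 with a floor of 3 counts per library, against a fitted 4.47), was 0.15 in reduced KSOM against E4.5, 0.29 in targeted OVX against OVX, 0.66 in depleted KSOM against OVX and −1.71 between the media with it. The genes Tyrobp, of that list, and Lcn2, which neutrophils also express, went from 11.28 and 7.01 between the media to −4.39 and −1.79. Leaving out libraries moved oxidative phosphorylation from −0.19 to 0.57 in starvation against E4.5 and from −0.38 to 1.03 in targeted OVX against OVX. It moved blood cell genes from −3.66 to 0.28 in targeted OVX and from −4.57 to 0.66 in depleted KSOM, both against OVX. Apart from the shift of all genes with library totals, the cause of these changes was not tested.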

Other observations

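The added tests of tissue markers and the 8 genes drawn per library were chosen after the data were seen. Glycolysis genes were higher in OVX than in E4.5, with 5 of 29 called higher, 0 lower and 24 not passing, and 7 higher and 1 lower adjusted over the list alone (median 0.93, adjusted p = 0.0049, and adjusted p = 0.3 with an estimated correlation). With library totals the median was 0.34 (adjusted p = 0.078). Ldhb, the lactate dehydrogenase subunit of oxidative tissues, rose 32.7-fold (5.03 ± 0.92 SE, n = 2 and 2, adjusted p = 0.017; 0.11 without E4.5 replicate 2). Trophectoderm genes were also higher in starvation than in E4.5, with 4 of 28 called higher, 0 lower and 24 not passing, and 6 higher and 0 lower adjusted over the list alone (median 0.7, adjusted p = 2e-04, and adjusted p = 0.2 with an estimated correlation). Their median was 0.28 without starvation replicate 1, 1.08 without E4.5 replicate 2 and 0.46 with library totals.

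By chi-square per degree of freedom, replicates of a group differed most in OVX and starvation, at 624 and 561 between the 2 libraries. That measure allows for counting error only. It grows with library depth and takes amplified reads as separate molecules. The lowest rank correlation between replicates of a group was 0.84 to 0.89. Malat1 took 7.23% and 2.63% of counts in OVX and 5.06%, 4.49% and 4.68% in reduced KSOM, against 0.23% and 0.4% in E4.5.

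The list of uterine epithelium and stroma genes, fixed in advance, was higher than in E4.5 in OVX (2 of 22 called higher, 0 lower and 20 not passing; 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.037, and adjusted p = 0.43 with an estimated correlation), in starvation (1, 0 and 21; 2 and 0; adjusted p = 0.0064, and 0.54) and in reduced KSOM (2, 0 and 20; 2 and 0; adjusted p = 1.1e-05, and 0.34). It was also higher in reduced than in depleted KSOM (2, 1 and 19; 6 and 1; adjusted p = 0.0039, and adjusted p = 0.4 with an estimated correlation). Many of its genes were at or near 0, and the fitted medians of 2.7, 5.55, 5.14 and 5.3 became 1.63, 3.75, 2.91 and 2.88 with counts raised to a floor of 3 per library. The call was lost in OVX without E4.5 replicate 1 (adjusted p = 0.14), E4.5 replicate 2 (0.055) or OVX replicate 1 (0.17), in starvation without starvation replicate 2 (0.7), and with the term for muscle-bearing libraries in OVX (0.14) and between the media (0.47). In reduced KSOM against E4.5 it was kept with that term (fitted median 2.45), and its called genes were Ltf and Lcn2.

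Fibroblast and stroma genes were higher in reduced than in depleted KSOM, with 0 of 12 called over all genes and 3 higher and 0 lower adjusted over the list alone (median 3.89 at that floor, adjusted p = 0.0063, and adjusted p = 0.33 with an estimated correlation).

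None of the 7 Y-linked genes was called in any comparison by edgeR over all genes. As a list they were lower in starvation than in E4.5 (4 lower and 0 higher adjusted over the list alone; median −5.94 with the floor of 3 counts per library, adjusted p = 0.026, and adjusted p = 0.68 with an estimated correlation) and than in OVX (0 either way; −4.94, adjusted p = 0.0099, and 0.6). They were higher in depleted KSOM than in E4.5 (0 either way; 2.48, adjusted p = 0.048, and 0.62) and than in OVX (0 either way; 2.66, adjusted p = 0.012, and 0.67). The starvation calls were lost without starvation replicate 1 (adjusted p = 0.25 against E4.5 and 0.12 against OVX) or 2 (0.13 and 0.057), without E4.5 replicate 2 (0.86) and without OVX replicate 1 (0.3). The depleted KSOM calls were lost against E4.5 without E4.5 replicate 1 (0.53) or depleted KSOM replicate 1 (0.054) or 2 (0.11), and against OVX without OVX replicate 2 (0.36). Length and GC offsets ended the call of depleted KSOM against E4.5 (0.054), and the term for muscle-bearing libraries ended that call (0.054) and the call of starvation against OVX (0.24). Whether the groups differed in the sex of their embryos was not tested.

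Other tissues left fainter traces, given as sums over marker genes under 5 CPM in E4.5. Liver genes summed to 87.6 CPM in starvation replicate 2 and to 81.8 and 92.2 CPM in reduced KSOM replicates 1 and 3, and lymphocyte genes to 195 CPM in OVX replicate 1 and 57.8, 52.9 and 70.2 CPM in reduced KSOM, against at most 24.5 CPM elsewhere. Erythroid genes summed to 179 CPM in depleted KSOM replicate 1 and 238 CPM in reduced KSOM replicate 3. Airway epithelium genes summed to 57.2 and 60.9 CPM in reduced KSOM replicates 1 and 3 and to 25.5 and 31 CPM in targeted OVX. On this basis neural genes reached 3.63 CPM and spermatid genes 6.36 CPM at most, and the neural sum over all 7 genes reached 78.7 CPM, in starvation replicate 2.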
